A study of Mus musculus with 14 samples.

How the data were processed

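RNA sequencing libraries of mouse small intestine were analysed from 14 samples: ileum or jejunum, each as crypt cells (3 libraries), LGR5 cells (2) and CD166 cells (2). Per the labels, tissue came from 5 to 8 cm from the cecum (ileum) or the pylorus (jejunum), sorted cells went straight into lysis buffer, and TruSeq libraries were read as single-end 50-base reads on an Illumina HiSeq. The submitters' processing notes name the mm9 genome and DESeq, without a version or a step; the aligner, the counting program and the annotation are not given in the sources used here. No mm9 annotation was at hand, so genes are given by symbol and Ensembl identifier as in the files, without coordinates.

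For each sample the authors deposited 2 files of 36401 genes (33018 distinct symbols). One kind, although named for RPKM, holds expected counts deposited without scaling: totals run from 6295828 to 20380369 per library, 50.6% of values above 0 are whole within 0.001, and 80.3% are multiples of 0.02 within 0.0004, as when a 50-base read is counted by its overlap with an exon. The other kind holds deposited log2 values: the log2 of the same count after 1 constant per library, with small values raised to a floor, minus the median of the gene over the 14 libraries. After 1 constant per library the kinds of file differed by at most 1.9e-06 over genes with more than 50 counts in every library. Fits on RPKM values, decided on earlier, were not run, since no RPKM values were found in the files.

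Expected counts were rounded to whole numbers and filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3; minimum count 10, minimum total 15), which kept 14750 genes. TMM factors scaled the libraries. One quasi-likelihood model (glmQLFit with robust estimation) held a mean for each of the 6 groups. The contrasts were ileum minus jejunum as the mean of the 3 within-population differences and within each population, the joint test of the region by population interaction, and LGR5 minus crypt, CD166 minus crypt and CD166 minus LGR5 as means over the regions. F-test p-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. Adjusted p-values of genes in the text come from this edgeR fit unless another tool is named. The standard error is the size of the log2 fold change divided by the square root of F. Values per library are TMM-normalised CPM, except for Xist and the Y-linked genes, given as CPM of the total count. Where a symbol occurs more than once, the entry with the highest mean count was used. Values of defensin, Reg, Cyp, Ces and Gm genes are uncertain wherever named, since reads may be shared between near-identical copies.

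The comparisons, tests, 27 gene lists (432 distinct genes, 427 of them in the files), the rule for naming genes and the first set of alternative fits were fixed before the data were examined. The rule named, among called genes with a mean log2 CPM of at least 3 and no overlap between the sides, the 12 with the largest change in each direction for the contrast over all populations and for each population contrast, and 5 for regions within a population. It also named up to 10 interaction genes, list members in order of mean level, and a fixed set of 11 region and sort marker genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation. List members were also adjusted over the list alone. For a principal component analysis log2 CPM of the 1000 most variable genes were used.

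Alternatives were DESeq2 size factors, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0 and limma-voom (limma 3.58.1) as the test, a fit of the compared groups alone, a replicate block and leaving out each library in turn. After the data were seen, further alternatives left out the library labelled ileum crypt 3 where it was not among the compared groups, that library with jejunum crypt 1, or the crypt libraries high in Xist. Others used a term for the latter, the deposited log2 values with limma, the sorted libraries alone, weights per library, or crossed replicate numbers. The recovery of known changes was tested on simulated data of the same design, with 200 genes changed 2-fold or 4-fold: 64.8% and 87.0% were recovered between regions over all populations, 18.8% and 66.3% in crypt, 6.8% and 61.6% in LGR5 and 15.3% and 70.6% in CD166. The recovery was 41.9% and 81.1% for LGR5 against crypt, 46.9% and 80.4% for CD166 against crypt, and 40.7% and 81.7% for CD166 against LGR5. Between 4 and 9 unchanged genes were called per simulation. Differences of 2-fold between regions within 1 population were mostly below what this design detects. Each simulated library was drawn from 1 mean per gene over all libraries, with genes independent. Differences between populations and unlike or near-identical libraries were therefore not modelled, and the shares may be too high for the real data. Gata4, for example, differed 14-fold between regions in LGR5 cells and was not called (adjusted p = 0.083).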

Results

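RNA was sequenced from epithelial cells of the ileum, taken near the cecum, and of the jejunum, taken near the pylorus, of C57Bl6 mice given as male and 6 to 12 weeks old. In each region 3 populations were collected: crypt cells (crypt), cells selected by LGR5, a receptor that marks crypt base columnar stem cells (LGR5), and sorted cells positive for CD44 and CD166 and low in CD24 (CD166). Each region had 3 crypt, 2 LGR5 and 2 CD166 libraries, 14 in all. Total expected counts per library ran from 6295828 to 20380369. The most abundant gene took 0.71% to 2.32% of the counts of a library. It was the lysozyme gene Lyz1, the defensin gene Defa24 or the stem cell gene Olfm4 in 10 of the 14 libraries. The labels do not say whether the libraries came from separate mice, so the p-values measure spread between these libraries.

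The main axis of expression separated crypt cells from sorted cells, and the next separated ileum from jejunum. The first component of the 1000 most variable genes held 59.8% of the variance and the second 14.1%. The library labelled ileum crypt 3 lay with the jejunum crypt libraries. Its normalised level of Fabp6, the ileal bile acid binding protein, was 25.8 CPM (counts scaled to library size), against 2688 and 1987 CPM in the other ileum crypt libraries. Jejunum crypt library 1 had 25.1 CPM of Fabp6. Gata4, a transcription factor of the proximal intestine, stood at 233 CPM in the library labelled ileum crypt 3 and at 28.0 and 45.4 CPM in the other ileum crypt libraries. Of all 91 pairs of libraries, the library labelled ileum crypt 3 and jejunum crypt 1 were the most alike. Between them 17.4% of genes differed by more than counting noise, where noise alone gives 5% and the next closest pair had 39%. The counts of genes called between regions, and the values that moved most, are therefore given with and without the library labelled ileum crypt 3, an alternative for which the doubt arose from the data. The female transcript Xist was also uneven: it reached 1758 CPM in ileum crypt 1 and 1158 CPM in jejunum crypt 2, whose Y-linked genes were at most 0.16 CPM. In the other 4 crypt libraries Xist was at most 3.03 CPM.

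**Figure D1:**
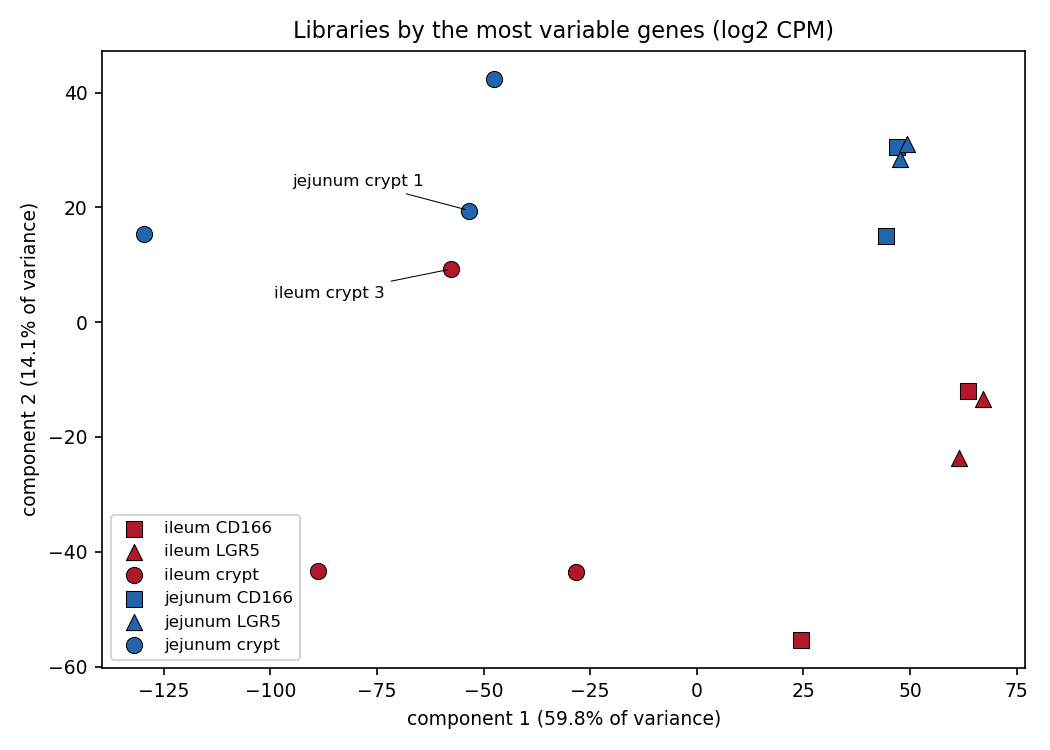
Each point is a library, placed by the first and second principal components of log2 CPM of the 1000 most variable genes, which hold 59.8% and 14.1% of the variance; colour gives the region and shape the population. The library labelled ileum crypt 3 lies beside jejunum crypt 1, and away from the other ileum crypt libraries.

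The first comparison asked which genes differ between ileum and jejunum when the 3 populations are weighted equally (7 ileal and 7 jejunal libraries). Genes of bile acid uptake and distal position were higher in the ileum. Fabp6 (ENSMUSG00000020405) was 229-fold higher (log2 7.84 ± 1.19 SE, adjusted p = 0.00714), and Slc10a2 (ENSMUSG00000023073), the apical bile acid transporter, was 12.4-fold higher (log2 3.63 ± 0.68). Slc10a2 differed by 5.54 ± 1.07 in crypt, 4.01 ± 1.27 in CD166 and only 1.34 ± 1.20 in LGR5 cells (adjusted p = 0.717). Its jejunal group means were at most 0.62 CPM. The homeobox genes Hoxb8 and Hoxb9 were 91.1-fold and 102-fold higher (log2 6.51 ± 0.73 and 6.68 ± 0.78, adjusted p = 0.00262 for each). Genes of lipid handling and proximal position were lower: Gata4 (ENSMUSG00000021944) was 7.97-fold lower (log2 -2.99 ± 0.50, adjusted p = 0.00962), Apoa4, an apolipoprotein of dietary fat transport, 11.4-fold lower (log2 -3.51 ± 0.77), and Lct (ENSMUSG00000026354), the lactase gene, 7.17-fold lower (log2 -2.84 ± 0.70, adjusted p = 0.0405).

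Other genes with large called differences, whose levels did not overlap between the regions in any population, were of mixed function. That rule also set the library labelled ileum crypt 3 against jejunum crypt 1, the pair most alike. Without that library, genes meeting the rule went from 70 to 217 higher and from 72 to 285 lower in the ileum. Onecut2, Afp, Mme and Defa20 were then among those named. Higher in the ileum were the defensin-like gene Gm15308 (log2 6.22 ± 0.86; uncertain, since reads may be shared between near-identical copies), the monocarboxylate transporter gene Slc5a8 (log2 3.55 ± 0.71), Mboat1 (3.39 ± 0.46), Naaladl1 (2.70 ± 0.30) and the fatty acid desaturase gene Scd2 (2.56 ± 0.37). The same direction held for the oxidase gene Duox2 (log2 2.39 ± 0.54), the goblet cell gene Clca3 (2.34 ± 0.41), Tspan1 (2.13 ± 0.29) and Cd177 (2.09 ± 0.30). Osr2 (ENSMUSG00000022330), a zinc finger gene, was 4.78-fold higher (log2 2.26 ± 0.49, adjusted p = 0.0244), although its crypt levels overlapped between the regions. That overlap lay only between the library labelled ileum crypt 3 and jejunum crypt 1. Lower in the ileum were Reg1 (log2 -4.47 ± 0.88; a gene of a family with near-identical copies), the arginase gene Arg2 (-3.56 ± 0.50), the fatty acid binding gene Fabp1 (-3.42 ± 0.77), Gkn3 (-3.30 ± 0.48) and Creb3l3, a transcription factor of lipid metabolism (-3.22 ± 0.39). Rbp2, which binds retinol, was lower by the same test (log2 -3.16 ± 0.69), as were Gsta1 (-3.12 ± 0.66), Adh6a (-3.05 ± 0.56), Apoc3 (-2.98 ± 0.64), Apoc2 (-2.87 ± 0.72) and Prap1 (-2.62 ± 0.35).

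**Figure D2:**
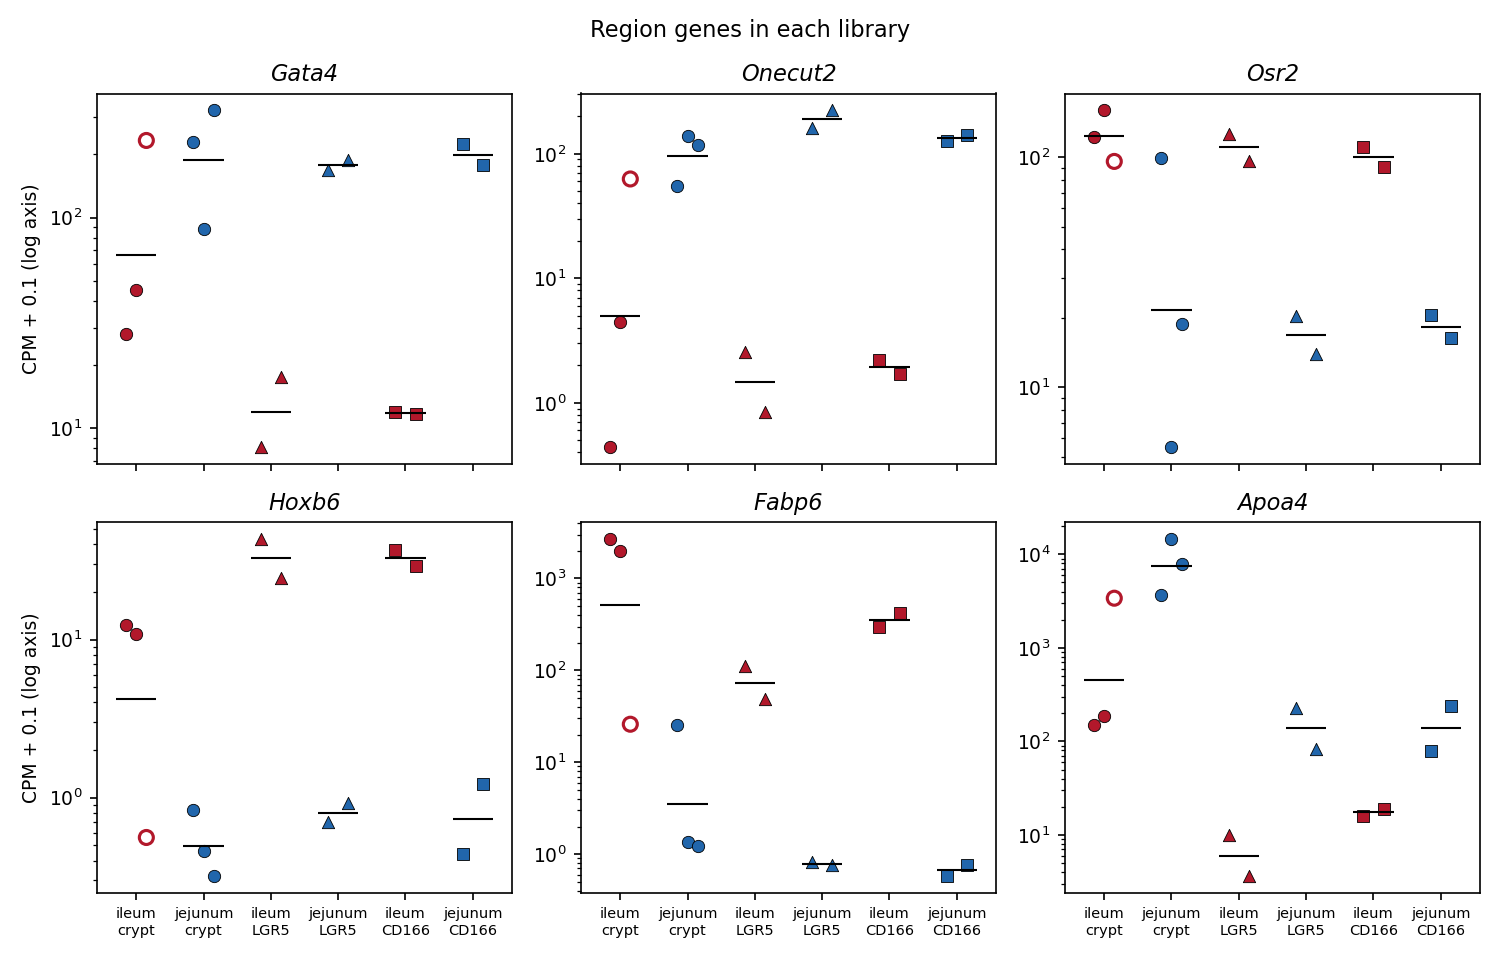
Normalised CPM plus 0.1 on a log axis in each library for Gata4, Onecut2, Osr2, Hoxb6, Fabp6 and Apoa4, by region (colour) and population; the bar is the geometric mean of a group and the open circle is the library labelled ileum crypt 3. Fabp6 lies at 48.4 CPM or above in the other 6 ileal libraries and at 25.1 CPM or below in the jejunal ones.

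By gene list, 9 of 14 measured genes of ileal function rose in the ileum and 1 fell, with a median log2 difference of 1.89 (camera adjusted p = 1.7e-14; adjusted p = 0.096 with an estimated correlation). Adjusted over the list alone, 11 rose and 1 fell. Guca2a, the guanylin gene, rose (log2 2.49 ± 0.36), as did the bile acid exporter gene Osta (0.74 ± 0.18). Nr0b2, a nuclear receptor gene of bile acid control, fell (-3.70 ± 0.70). Of 17 jejunal genes 11 fell and none of the others rose (13 fell adjusted over the list alone; median -2.99, camera adjusted p = 2.8e-20; adjusted p = 0.096 with an estimated correlation). The 35 positional transcription factors split, with 10 higher and 5 lower, or 15 and 7 adjusted over the list alone. Hoxb6 (log2 5.06 ± 0.63) and Hoxb7 (5.48 ± 0.75) rose with Hoxb8 and Hoxb9, and the proximal factors Pdx1 (-5.17 ± 0.82) and Onecut2 (-5.08 ± 0.83) fell. That list's median of 0.42 had a camera adjusted p = 4.3e-05, and an adjusted p = 0.15 with an estimated correlation.

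Absorptive and detoxifying genes were lower in the ileum as groups. Of 20 enterocyte markers 11 fell and 1 rose (14 and 1 adjusted over the list alone; median log2 -1.13, camera adjusted p = 4.7e-16; adjusted p = 0.11 with an estimated correlation). The brush border enzymes Anpep (log2 -1.10 ± 0.25) and Sis (-1.16 ± 0.21) fell, and Krt20, a keratin of mature cells, rose (1.08 ± 0.24). Of 19 genes of dietary lipid absorption 8 fell (14 adjusted over the list alone), among them Mttp, which loads lipid onto apolipoprotein B (-1.90 ± 0.33), and the triglyceride synthesis gene Dgat1 (-1.10 ± 0.15). Their median was -1.10 (camera adjusted p = 2.9e-15; adjusted p = 0.11 with an estimated correlation). Of 28 genes of xenobiotic metabolism 14 fell and 2 rose (24 and 2 adjusted over the list alone; median -1.49, camera adjusted p = 2.8e-20; adjusted p = 0.11 with an estimated correlation). Cyp3a11 (-3.47 ± 0.76), Ces2e (-1.26 ± 0.22) and Adh1 (-1.99 ± 0.49) fell, and the efflux pump gene Abcb1a (1.24 ± 0.13) and Gsta3 (1.57 ± 0.34) rose. Cyp and Ces genes are marked uncertain because near-identical copies share reads. Of 11 retinoid genes 3 fell, Rdh7 among them (-2.69 ± 0.47), or 6 adjusted over the list alone (camera adjusted p = 4.3e-05; adjusted p = 0.11 with an estimated correlation). Of 18 genes of fatty acid oxidation and PPAR targets 1 fell, Angptl4 (-1.71 ± 0.42), or 9 adjusted over the list alone (camera adjusted p = 4.2e-09; adjusted p = 0.21 with an estimated correlation). Several genes, such as Apoa4 and Lct, belong to more than 1 of these lists.

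Goblet cell genes, and some Paneth cell genes, were higher in the ileum. Of 14 goblet cell markers 7 rose (13 adjusted over the list alone), with a median log2 difference of 1.49 (camera adjusted p = 3.8e-16; adjusted p = 0.11 with an estimated correlation). They included Agr2, needed for mucin folding (1.74 ± 0.32), Creb3l1 (1.60 ± 0.30) and the secretory lineage factor Atoh1 (1.87 ± 0.34). Of 16 Paneth cell markers 4 rose (7 adjusted over the list alone; median 0.70, camera adjusted p = 4.9e-07; adjusted p = 0.31 with an estimated correlation): Mmp7 (1.82 ± 0.37), Wnt3 (1.88 ± 0.47), Defa21 (4.29 ± 0.81) and Defa22 (4.35 ± 0.80), the defensins again with shared reads. Enteroendocrine genes moved in both directions: of 22, the hormone genes Gcg (2.26 ± 0.37), Nts (3.66 ± 0.58) and Pyy (4.76 ± 0.58) rose and the serotonin synthesis gene Tph1 fell (-1.50 ± 0.24), and adjusted over the list alone 4 rose and 4 fell. As a list they had a median of -0.26, with 6 of 22 values above 0 (camera adjusted p = 0.19). In CD166 cells the median was -1.20 with 3 of 22 values above 0 (camera adjusted p = 1.3e-09; adjusted p = 0.39 with an estimated correlation), and in LGR5 cells it was 0.34 (camera adjusted p = 0.022; adjusted p = 0.7 with an estimated correlation); whether the list differs between populations was not tested. In CD166 cells alone the Paneth list had a median of -0.14 (camera adjusted p = 0.31). Among 14 defence genes 3 rose and 1 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.041, or 0.066 without the library labelled ileum crypt 3; adjusted p = 0.21 with an estimated correlation), with Reg3g (1.94 ± 0.43) and Duoxa2 (2.66 ± 0.52) higher and Reg1 lower. Of 20 genes of cholesterol synthesis and uptake 2 rose, Stard4 among them (0.64 ± 0.10; camera adjusted p = 5.6e-06; adjusted p = 0.28 with an estimated correlation). In the ileum crypt libraries 1 and 2 the mean log2 CPM of the Paneth list was 9.16 and 9.43, against 8.05 in the library labelled ileum crypt 3.

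None of the listed stem cell markers passed the test between regions. Of 24 crypt base columnar markers edgeR called 0, with 4 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. Their median log2 difference was 0.25 (camera adjusted p = 0.05, under the threshold before rounding; adjusted p = 0.79 with an estimated correlation). The list lost this call without ileum crypt 2 (adjusted p = 0.16), the library labelled ileum crypt 3 (0.099), jejunum crypt 2 (0.52), ileum LGR5 1 (0.53) or ileum CD166 1 (0.16), and without jejunum CD166 2 (median 0.21). Lgr5 (ENSMUSG00000020140) differed by log2 0.85 ± 0.28 (adjusted p = 0.116), Ascl2 by 0.32 ± 0.39, Olfm4 by 0.14 ± 0.29, Clca4 by 0.37 ± 0.38 and Slc12a2 by 0.31 ± 0.26. The sort markers Cd44 (0.21 ± 0.16), Cd24a (0.36 ± 0.24) and Alcam, which encodes CD166 (-0.07 ± 0.14), were not called either. The list tests for reserve stem cell, tuft, cell cycle, Wnt target, iron and calcium, lymphocyte, myeloid, stromal, red blood cell and sort marker genes missed the threshold, at adjusted p from 0.13 to 0.78. The red blood cell list had an adjusted p = 0.033 without the library labelled ileum crypt 3. Within 1 population some of these lists were called: in crypt cells the cell cycle (median 0.40, adjusted p = 3.1e-05), Wnt target (0.0056), stromal (0.011), red blood cell (0.002) and sort marker (0.018, or 0.054 without the library labelled ileum crypt 3) lists. The same held for the stem cell list in crypt (median 0.51, 1e-06), the tuft list in LGR5 cells (0.00061), and the lymphocyte (0.0056) and stromal (0.0078) lists in CD166 cells. Each missed the threshold with an estimated correlation (adjusted p from 0.26 to 0.58). Among crypt libraries, jejunum crypt 2 was lowest in mean log2 CPM of the cell cycle (5.21), stem cell (4.69) and Wnt target (3.68) lists. The other crypt libraries of both regions lay at 6.38 to 6.57, 6.04 to 6.82 and 4.42 to 5.03. These 3 crypt calls may therefore rest mainly on that library. The stromal list was higher in ileal crypt cells (median 1.02) but lower in ileal CD166 cells (-1.16). In CD166 cells its mean log2 CPM was low throughout. It was -2.21 in ileum CD166 2 and 0.32 in ileum CD166 1, against 0.49 and 0.37 in the jejunal libraries. The fall thus lay mainly in 1 library. The lymphocyte list was higher in ileal CD166 cells (median 1.78), where its level was 2.49 in ileum CD166 2 and -1.48 in ileum CD166 1. Over all populations Slc11a2 (-0.51 ± 0.12), of the iron and calcium list, fell and Itgam (1.49 ± 0.29), of the myeloid list, rose. The Notch list (adjusted p = 0.0038; 0.15 as adjusted p with an estimated correlation) had 1 called gene, Atoh1. MHC class II genes (0.0048; adjusted p = 0.5 with an estimated correlation) had a median of 1.37 and immediate early genes (0.00049; adjusted p = 0.45 with an estimated correlation) a median of -0.70, and edgeR called 0 members of either. At an unadjusted p under 0.05 these had 1 and 6, and DESeq2 and limma-voom called 0.

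In all, edgeR called 739 of 14750 genes between the regions, 441 higher and 298 lower in the ileum, of which 550 differed at least 2-fold. Without the library labelled ileum crypt 3 it called 1269, which include 733 of the 739. In that fit several jejunal genes differed by over 1.5 times more than with the library: Onecut2 was 73.3-fold lower (log2 -6.20 ± 0.47), Reg1 37.5-fold (-5.23 ± 0.75), Apoa4 22.2-fold (-4.47 ± 0.49), Fabp1 20.5-fold (-4.35 ± 0.50), Rbp2 16.9-fold (-4.08 ± 0.35), Cyp3a11 16.9-fold (-4.08 ± 0.64), Adh6a 13.1-fold (-3.72 ± 0.29), Lct 13.1-fold (-3.71 ± 0.38) and Apoc2 11-fold (-3.46 ± 0.61). Without 1 other library the count moved by over 1.5 times for 10 more: jejunum crypt 2 (1115), jejunum crypt 3 (487), ileum LGR5 1 (479) and 2 (249), jejunum LGR5 1 (165) and 2 (138), ileum CD166 1 (345) and 2 (242), and jejunum CD166 1 (242) and 2 (141). Of 78 called genes followed for this comparison, 34 kept the call in each of the 14 fits without 1 library. Gata4, Hoxb6, Hoxb7, Hoxb8, Hoxb9, Guca2a, Pyy, Gkn3, Creb3l3, Dgat1 and Abcb1a were among them. Fabp6, Slc10a2, Defa21, Defa22 and Agr2 lost the call without any 1 of the 4 jejunal sorted libraries. Apoc2 lost the call in 12 of the 14 fits, Adh1 and Angptl4 in 11 each, and Wnt3 and Osta in 10 each. Apoa4, Lct, Fabp1, Osr2 and Reg1 lost it in 7 to 10 of the fits.

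Within the crypt cells (3 libraries per region), edgeR called 0 genes between ileum and jejunum, with 1899 at an unadjusted p under 0.05, 323 called by DESeq2 and 0 by limma-voom. Fabp6 differed by log2 7.40 ± 1.62 (adjusted p = 0.252), Slc10a2 by 5.54 ± 1.07, Gata4 by -1.07 ± 0.69 and Lct by -1.20 ± 0.94. Without the library labelled ileum crypt 3, edgeR called 614 genes. In that fit Fabp6 was 251-fold higher in the ileum (log2 7.97 ± 1.18, adjusted p = 0.00615) and Slc10a2 68.8-fold higher (6.10 ± 0.56), while Lct was lower (-3.80 ± 0.62) and Gata4 5.85-fold lower (-2.55 ± 0.52, adjusted p = 0.0259). Besides Fabp6, the naming rule gave higher values of Gm15308 (6.41 ± 0.86), Plb1 (6.38 ± 0.73), Tmigd1 (5.88 ± 0.73) and Mgat4c (5.33 ± 0.79), and lower values of Akp3 (-8.90 ± 2.11), Reg1 (-7.07 ± 1.38), Apoc2 (-5.74 ± 1.13), Apoa4 (-5.68 ± 0.88) and Cyp2b10 (-5.58 ± 0.79). Leaving out ileum crypt 1 instead gave 80 genes, and leaving out jejunum crypt 1 gave 100. Lymphocyte markers were uneven in this comparison: their mean log2 CPM was 6.09 in ileum crypt 1 and 6.45 in jejunum crypt 2, the libraries with high Xist, and 2.98 to 3.74 in the other 4.

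Within the LGR5 cells (2 libraries per region), 84 of 103 called genes were higher in the ileum. Clca3 was 30.3-fold higher (log2 4.92 ± 0.85, adjusted p = 0.0438), Bcas1 20.6-fold (4.37 ± 0.69), the actin severing gene Scin 16.4-fold (4.04 ± 0.70), Fer1l6 14.8-fold (3.89 ± 0.70) and Spats2l 12.8-fold (3.68 ± 0.62). Gkn3 (ENSMUSG00000030048) was 27.2-fold lower (-4.77 ± 0.93, adjusted p = 0.0466), and Cttnbp2 (-2.21 ± 0.41), Ugt1a6a (-2.05 ± 0.30; exons shared within its gene cluster), the thiamine transporter gene Slc19a2 (-2.02 ± 0.30) and the amino acid transporter gene Slc3a1 (-1.81 ± 0.27) were lower too. Hoxb8 (8.34 ± 1.43), Hoxb9 (7.99 ± 1.49), Guca2a (3.52 ± 0.69), Abcb1a (2.33 ± 0.25), Reg4 (2.35 ± 0.46) and Creb3l1 (3.12 ± 0.57) were called higher, and Creb3l3 (-4.62 ± 0.81) and Dgat1 (-1.52 ± 0.28) lower. Of 14 goblet markers 2 rose, or 13 adjusted over the list alone, with a median of 2.64 (camera adjusted p = 8.4e-19; adjusted p = 0.26 with an estimated correlation). The mean log2 CPM of that list was 7.53 and 9.08 in the ileal LGR5 libraries and 6.03 and 5.55 in the jejunal ones. Of tuft, Paneth and enteroendocrine markers edgeR and limma-voom called 0, with 3, 6 and 4 higher at an unadjusted p under 0.05 and 1, 4 and 4 called by DESeq2. All 12 tuft values were above 0, with a median of 1.37 (camera adjusted p = 0.00061; adjusted p = 0.51 with an estimated correlation). The Paneth list, with 11 of 16 values above 0, had a camera adjusted p = 0.0045, and the enteroendocrine list, with 16 of 22, had 0.022 (each with adjusted p = 0.7 with an estimated correlation). Tuft and enteroendocrine levels were high mainly in ileum LGR5 2 (5.24 and 4.15), against 3.56 and 2.68 in ileum LGR5 1 and at most 3.33 and 2.79 in the jejunal LGR5 libraries. Of the 24 stem cell markers edgeR called 0, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. Lgr5 differed by 0.26 ± 0.51 and Olfm4 by -0.43 ± 0.53.

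edgeR called 103 genes between the regions in LGR5 cells (84 higher, 19 lower); the split was 560 and 213 with DESeq2, 18 and 12 with limma-voom, and 847 and 727 in a fit of those groups alone. The count was 357 without the library labelled ileum crypt 3, which enters only through the shared spread, and 159, 4, 3 and 2 without ileum LGR5 1, ileum LGR5 2, jejunum LGR5 1 and jejunum LGR5 2. Every called gene named above for LGR5 cells lost its call in 2 to 4 of these fits. The sizes moved too: without ileum LGR5 2, Clca3 was at log2 3.09, Scin at 2.35 and Fer1l6 at 2.15, and without jejunum LGR5 1 Clca3 was at 6.00. In CD166 cells (2 libraries per region) 3 genes were called, named here because they were so few. Unc5b, a netrin receptor gene, was 3.69-fold higher in the ileum (log2 1.89 ± 0.23, adjusted p = 0.0253), Rdh9 21.2-fold higher (4.40 ± 0.54) and Tph1 13.1-fold lower (-3.71 ± 0.46, adjusted p = 0.0253). Tph1 stood at 62.8 and 83.2 CPM in the jejunal CD166 libraries and at 4.80 and 6.31 CPM in the ileal ones. The enteroendocrine list, which includes Tph1, had mostly lower values. Of its 22 members only Tph1 was called lower over all genes. Adjusted over the list alone 7 were lower and 3 higher, and at an unadjusted p under 0.05 12 were lower and 3 higher. Without any 1 of the 4 CD166 libraries edgeR called 0 genes in CD166 cells, and without the library labelled ileum crypt 3 it called 112. In the full fit 938 had an unadjusted p under 0.05, DESeq2 called 186 and limma-voom 47.

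The direction found in LGR5 cells was compared with that in the other populations, which share no library with them. Of the 103 genes called in LGR5 cells, 88.3% had the same sign in CD166 cells and 90.3% in crypt cells, against 53.2% and 58.5% of all genes. Across genes, which are not independent replicates, the log2 differences in LGR5 and CD166 cells had r = 0.39 (rho = 0.20), and those in LGR5 and crypt cells r = 0.43 (rho = 0.31). With a separate fit per population these shares were 72.8% of 1564 and 79.1% of 1460 genes, and without the library labelled ileum crypt 3 they were 91.0% and 93.0% of 357 genes. A test of whether the region difference depends on the population called 2 genes. Unc5b (ENSMUSG00000020099) differed by log2 0.25 ± 0.18 in crypt, 2.92 ± 0.24 in LGR5 and 1.89 ± 0.23 in CD166 cells (adjusted p = 0.0367). C530008M17Rik (ENSMUSG00000036377) differed by 0.05 ± 0.16, 2.50 ± 0.21 and 0.32 ± 0.19 (adjusted p = 0.0367). The count was 15 without ileum crypt 1, 1 without ileum LGR5 1, 3 without jejunum crypt 2, and 0 without any other 1 library.

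**Figure D3:**
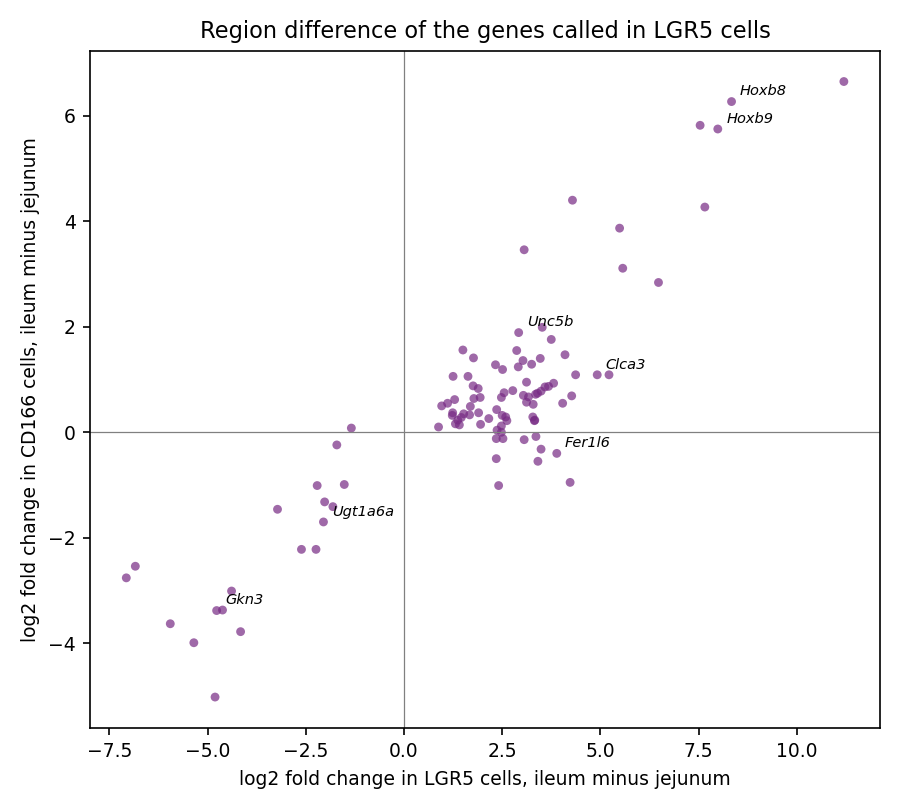
Each point is 1 of the 103 genes called between regions in LGR5 cells; the axes give its log2 fold change, ileum minus jejunum, in LGR5 cells (horizontal) and in CD166 cells (vertical). Of these genes 88.3% lie on the same side of 0 on both axes.

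The next comparisons set each sorted population against crypt cells, with the regions weighted equally. The crypt cells are not described as sorted, so these differences cannot be told apart from effects of sorting and handling. Xist and Y-linked genes occurred together in the sorted libraries only, so a difference in the mix of sexes cannot be told apart either. In LGR5 cells (4 libraries, against 6) stem cell genes were higher: Lgr5 was 5.48-fold higher (log2 2.45 ± 0.33, adjusted p = 0.000428), the stem cell factor Ascl2 3.59-fold (1.84 ± 0.46) and Olfm4 4.68-fold (2.23 ± 0.34). Lgr5 was used for sorting and serves as a label check. Lgr5, Ascl2, Axin2, Rnf43, Znrf3 and Ephb2 are in both the stem cell and the Wnt target list below. Olfm4 is in both the stem cell and the Notch list, so these lists are not separate support. Of 24 stem cell markers 21 rose (23 adjusted over the list alone; median 1.73, camera adjusted p = 6.2e-19; adjusted p = 0.13 with an estimated correlation), Clca4 (2.07 ± 0.45), Slc12a2 (2.00 ± 0.31) and Smoc2 (1.64 ± 0.27) among them. All 20 enterocyte markers fell, such as Fabp2 (-3.87 ± 0.64) and Anpep (-4.18 ± 0.36), with a median of -4.16 (camera adjusted p = 3e-36; adjusted p = 0.074 with an estimated correlation). Of 16 Paneth markers 11 fell (13 adjusted over the list alone; camera adjusted p = 0.0017; adjusted p = 0.46 with an estimated correlation), including Lyz1 (-1.56 ± 0.41), Defa24 (-1.31 ± 0.38) and Itln1 (-1.76 ± 0.43). Of 14 Wnt targets 9 rose, Axin2 (1.72 ± 0.33) and Sox4 (1.88 ± 0.30) among them, and Notum, a Wnt inhibitor gene, fell (-2.93 ± 0.81); adjusted over the list alone 10 rose and 1 fell (camera adjusted p = 3.4e-06; adjusted p = 0.18 with an estimated correlation). Of 11 Notch genes 6 rose, among them Notch1 (1.62 ± 0.17), Notch2 (1.04 ± 0.15), Dll1 (1.26 ± 0.24) and Hes1 (1.23 ± 0.26), the same number adjusted over the list alone (camera adjusted p = 3.5e-06; adjusted p = 0.074 with an estimated correlation).

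Immune and enterocyte genes were among the genes the naming rule gave as lower in LGR5 than in crypt cells, and immediate early genes among those it gave as higher. Lymphocyte genes were lower: Cd7 by 172-fold (log2 -7.42 ± 1.19), the granzyme genes Gzma and Gzmb by 162-fold each (-7.34 ± 1.53 and -7.34 ± 1.32), Ccl5 (-7.36 ± 1.30), Gimap4 (-7.27 ± 1.27), Il2rb (-7.26 ± 1.29), Cd8a (-6.99 ± 1.36), Coro1a (-6.93 ± 1.29), Hmha1 (-6.63 ± 1.15) and Pik3cd (-6.51 ± 1.15), along with Cyp3a11 (-6.68 ± 1.10) and Apoa4 (-6.67 ± 1.13). Of 17 lymphocyte markers 13 fell (15 adjusted over the list alone; median -6.08, camera adjusted p = 3.4e-06; adjusted p = 0.3 with an estimated correlation), 8 of 11 myeloid, 6 of 15 stromal and all 5 red blood cell markers fell, Hbb-b1 by 80.5-fold (-6.33 ± 0.77). The lymphocyte list had a mean log2 CPM of 2.98 to 6.45 in the crypt libraries and of -1.20 to -0.13 in the LGR5 libraries. It was highest in the crypt libraries high in Xist, and without these Gzma was at -5.17 and Cd8a at -5.08. Immediate early genes were higher in LGR5 cells: Egr1 17.9-fold (4.16 ± 0.63), Dusp1 (3.80 ± 0.59), Jun 11.3-fold (3.50 ± 0.46), Fos 10.5-fold (3.39 ± 0.55) and Atf3 6.01-fold (2.59 ± 0.73). This was not particular to LGR5 cells. The mean log2 CPM of the immediate early list was 3.21 to 4.42 in the crypt libraries and 4.86 to 7.43 in the LGR5 and CD166 libraries. Between CD166 and LGR5 cells its median difference was 0.04. Of 17 such genes 11 rose, both over all genes and adjusted over the list alone (median 2.59, camera adjusted p = 1.2e-07; adjusted p = 0.25 with an estimated correlation), the heat shock gene Hspa1a among them (4.29 ± 1.22). Cyr61 (4.04 ± 0.79), Ceacam10 (3.24 ± 0.45), Cyp2e1 (2.93 ± 0.42), Ifitm3 (2.83 ± 0.30), Thbs1 (2.78 ± 0.57), Pxdn (2.77 ± 0.49) and Nox1 (2.54 ± 0.42) were higher as well.

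edgeR called 4639 genes between LGR5 and crypt cells, 1914 higher and 2725 lower. The count was 2459 without ileum LGR5 1, 2675 without jejunum LGR5 1 and 2421 without jejunum LGR5 2. Of 31 cell cycle genes 30 had values above 0, with a median of 0.39 (camera adjusted p = 0.002; adjusted p = 0.5 with an estimated correlation). In all 4 rose, Mcm2 among them (0.81 ± 0.26), and the inhibitor gene Cdkn1a fell (-2.02 ± 0.22). Adjusted over the list alone, 0 rose, where 4 had risen over all genes, and 1 fell. Among 12 tuft cell markers 5 rose, such as Trpm5 (1.43 ± 0.37), and among 14 goblet markers Galnt12 rose (1.08 ± 0.30) and Zg16 fell (-2.05 ± 0.48). The sort markers Cd44 (1.87 ± 0.18) and Cd24a (1.00 ± 0.28) were higher, and Alcam was not called (0.16 ± 0.16). Lyz1, Defa24, Itln1, Atf3, Hspa1a, Mcm2, Trpm5, Galnt12, Notum, Cd24a and Ascl2 lost the call without 1 to 6 of the 10 libraries taken 1 at a time; without ileum LGR5 1, for example, Ascl2 had an adjusted p = 0.0675.

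CD166 cells (4 libraries, against 6 of crypt cells) were higher in hormone genes. The somatostatin gene Sst (ENSMUSG00000004366) was 30.1-fold higher (log2 4.91 ± 0.37, adjusted p = 2.34e-05), Gip 22.5-fold (4.49 ± 0.75), the potassium channel regulator gene Abcc8 22.2-fold (4.47 ± 0.36) and the endocrine transcription factor gene Isl1 14.4-fold (3.84 ± 0.29). Fabp5 (3.77 ± 0.34), Rbp4 (3.73 ± 0.35), Scgn (3.68 ± 0.41), Cpe, a prohormone processing enzyme (3.54 ± 0.41), and Gfra3 (3.47 ± 0.41) were higher as well. Of 22 enteroendocrine markers 15 rose and 1 fell (19 and 1 adjusted over the list alone; median 2.24, camera adjusted p = 1.6e-16; adjusted p = 0.14 with an estimated correlation). Chgb (2.17 ± 0.51) and Pyy (1.81 ± 0.56) rose, and Nts fell (-2.34 ± 0.65). Of 12 tuft cell markers 9 rose (10 adjusted over the list alone; median 2.11, camera adjusted p = 1.8e-06; adjusted p = 0.28 with an estimated correlation), with Dclk1 (2.04 ± 0.43), Trpm5 (2.27 ± 0.38) and Rgs13 (2.37 ± 0.49). Of 24 stem cell markers 20 rose (21 adjusted over the list alone; median 1.24, camera adjusted p = 1.2e-09; adjusted p = 0.3 with an estimated correlation), including Lgr5 (1.78 ± 0.33), Olfm4 (1.90 ± 0.34), Ascl2 (1.35 ± 0.45), Clca4 (1.58 ± 0.45) and Slc12a2 (1.38 ± 0.31). Of 16 Paneth markers 5 rose, the same number adjusted over the list alone (camera adjusted p = 0.00071; adjusted p = 0.44 with an estimated correlation), Mmp7 (2.04 ± 0.42), Defa24 (1.18 ± 0.36) and Gm15284 (1.14 ± 0.31) among them, the last 2 with reads shared between copies.

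As in LGR5 cells, enterocyte and immune genes were lower in CD166 cells than in crypt cells. All 20 enterocyte markers fell (median -3.49, camera adjusted p = 4.3e-32; adjusted p = 0.13 with an estimated correlation), such as Apoa4 (-5.96 ± 1.09), Anpep (-3.57 ± 0.34) and Fabp2 (-3.55 ± 0.63). Of 17 lymphocyte markers 10 fell, or 11 with 1 higher adjusted over the list alone (median -5.64, camera adjusted p = 2.7e-05; adjusted p = 0.32 with an estimated correlation), and all 5 red blood cell markers fell. Among the genes that met the naming rule, the largest falls were in Gzma (-8.36 ± 1.60), Cd8a (-8.29 ± 1.46), Gzmb (-8.21 ± 1.38), Cd7 (-7.86 ± 1.21), Ccl5 (-7.79 ± 1.31) and Itgae (-6.73 ± 1.32), then in Enpp7 (-6.65 ± 0.79), Hbb-b1 (-6.21 ± 0.75), Clca6 (-6.09 ± 1.22), Slc28a1 (-6.05 ± 0.97), Cyp3a11 (-6.04 ± 1.05) and Pdzk1 (-6.02 ± 0.45). The library ileum CD166 2 had a lymphocyte list level of 2.49, against -0.13 or less in the other CD166 libraries. Immediate early genes rose here too, 9 of 17 (10 adjusted over the list alone; median 2.58, camera adjusted p = 2.2e-06; adjusted p = 0.32 with an estimated correlation): Egr1 (4.10 ± 0.63), Dusp1 (3.90 ± 0.60), Atf3 (3.40 ± 0.74), Fos (3.29 ± 0.55) and Jun (3.25 ± 0.45). Goblet genes went both ways, Spink4 (1.40 ± 0.36) and Retnlb (3.28 ± 0.56) up and Zg16 (-2.11 ± 0.48) down, and Notch1 (1.20 ± 0.17) was higher. Of the genes of the sort markers, Cd44 was higher (1.87 ± 0.18), Alcam, which encodes CD166, was not called (0.02 ± 0.16, adjusted p = 0.936), and Cd24a was 3.06-fold higher (1.62 ± 0.28). The cells are described as low in CD24, but that gate acts on protein and these values are of RNA. edgeR called 4439 genes, 2008 higher and 2431 lower, and 2943, 2769 and 2823 without ileum CD166 1, ileum CD166 2 and jejunum CD166 2. Defa24, Ascl2, Clca4, Chgb, Gm15284, Nts, Pyy and Spink4 lost the call without 1 to 7 of the 10 libraries taken 1 at a time, Ascl2 most often.

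Between the sorted populations (4 libraries each), enteroendocrine and Paneth genes were higher in CD166 than in LGR5 cells. Sst was 57.3-fold higher (log2 5.84 ± 0.46, adjusted p = 0.000325), Gip 53.4-fold (5.74 ± 0.94), the secretogranin gene Scg2 22.2-fold (4.47 ± 0.55), the secretin gene Sct 13.9-fold (3.80 ± 0.37) and the cholecystokinin gene Cck 12.3-fold (3.62 ± 0.57). Rbp4 (4.45 ± 0.43), Cpe (4.14 ± 0.50), Fabp5 (3.91 ± 0.40), Abcc8 (3.90 ± 0.41), Scgn (3.78 ± 0.49), Gng4 (3.67 ± 0.53) and Isl1 (3.51 ± 0.33) followed. Of 22 enteroendocrine markers 15 rose, Chgb among them (2.99 ± 0.60), or 19 adjusted over the list alone. The median was 2.74 and the camera adjusted p = 1.3e-59. This was the 1 list of the 81 tests between populations still called with an estimated correlation (adjusted p = 0.027 with an estimated correlation). Of 16 Paneth markers 9 rose (15 adjusted over the list alone; median 2.40, camera adjusted p = 2.9e-34; adjusted p = 0.078 with an estimated correlation), with Lyz1 5.41-fold (2.44 ± 0.44), Defa24 5.62-fold (2.49 ± 0.43) and Itln1 5.30-fold (2.41 ± 0.46) higher. The enteroendocrine list had a mean log2 CPM of 4.91 to 6.39 in the CD166 libraries and 2.63 to 4.15 in the LGR5 libraries. Other lists moved less: myeloid (median 1.65, camera adjusted p = 0.031), defence (0.67, 0.028) and enterocyte genes (0.45, 0.0099) were higher in CD166 cells. Wnt target (-0.47, 0.0083) and Notch genes (-0.34, 0.028) were lower. These 5 lists missed the threshold with an estimated correlation (adjusted p from 0.62 to 0.89).

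Of 24 stem cell markers edgeR called 0 between CD166 and LGR5 cells, with 6 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. All 24 had values below 0, with a median of -0.49 (camera adjusted p = 3.3e-07; adjusted p = 0.67 with an estimated correlation). Lgr5 stood at -0.67 ± 0.36 (adjusted p = 0.625), Ascl2 at -0.50 ± 0.50 and Olfm4 at -0.33 ± 0.38. Of 14 goblet markers edgeR called 0 (2 at an unadjusted p under 0.05, 2 by DESeq2, 1 by limma-voom), with a median of 0.19. Of 12 tuft markers it called 0 as well (2 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom), with a median of 0.87 (camera adjusted p = 0.00091; adjusted p = 0.67 with an estimated correlation). Cd44 (0.00 ± 0.20), Cd24a (0.62 ± 0.31) and Alcam (-0.14 ± 0.18) were not called. edgeR called 238 genes, each of them higher in CD166 cells; 0 were lower, with 287 lower at an unadjusted p under 0.05, 22 lower by DESeq2 and 1 by limma-voom. The count was 85, 154, 86 and 93 without ileum LGR5 1 and 2 and jejunum LGR5 1 and 2, and 122, 139 and 131 without ileum CD166 2 and jejunum CD166 1 and 2. Sst, Scg2, Rbp4, Cpe, Fabp5, Abcc8, Sct, Scgn and Isl1 were called in each fit without 1 library. Gip, Gng4 and Cck lost the call without each of 3 LGR5 libraries (ileum 1, jejunum 1 and 2). Chgb, Lyz1, Defa24 and Itln1 lost it in 5 to 8 of 9 fits (adjusted p up to 0.229, 0.143, 0.109 and 0.178).

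**Figure D4:**
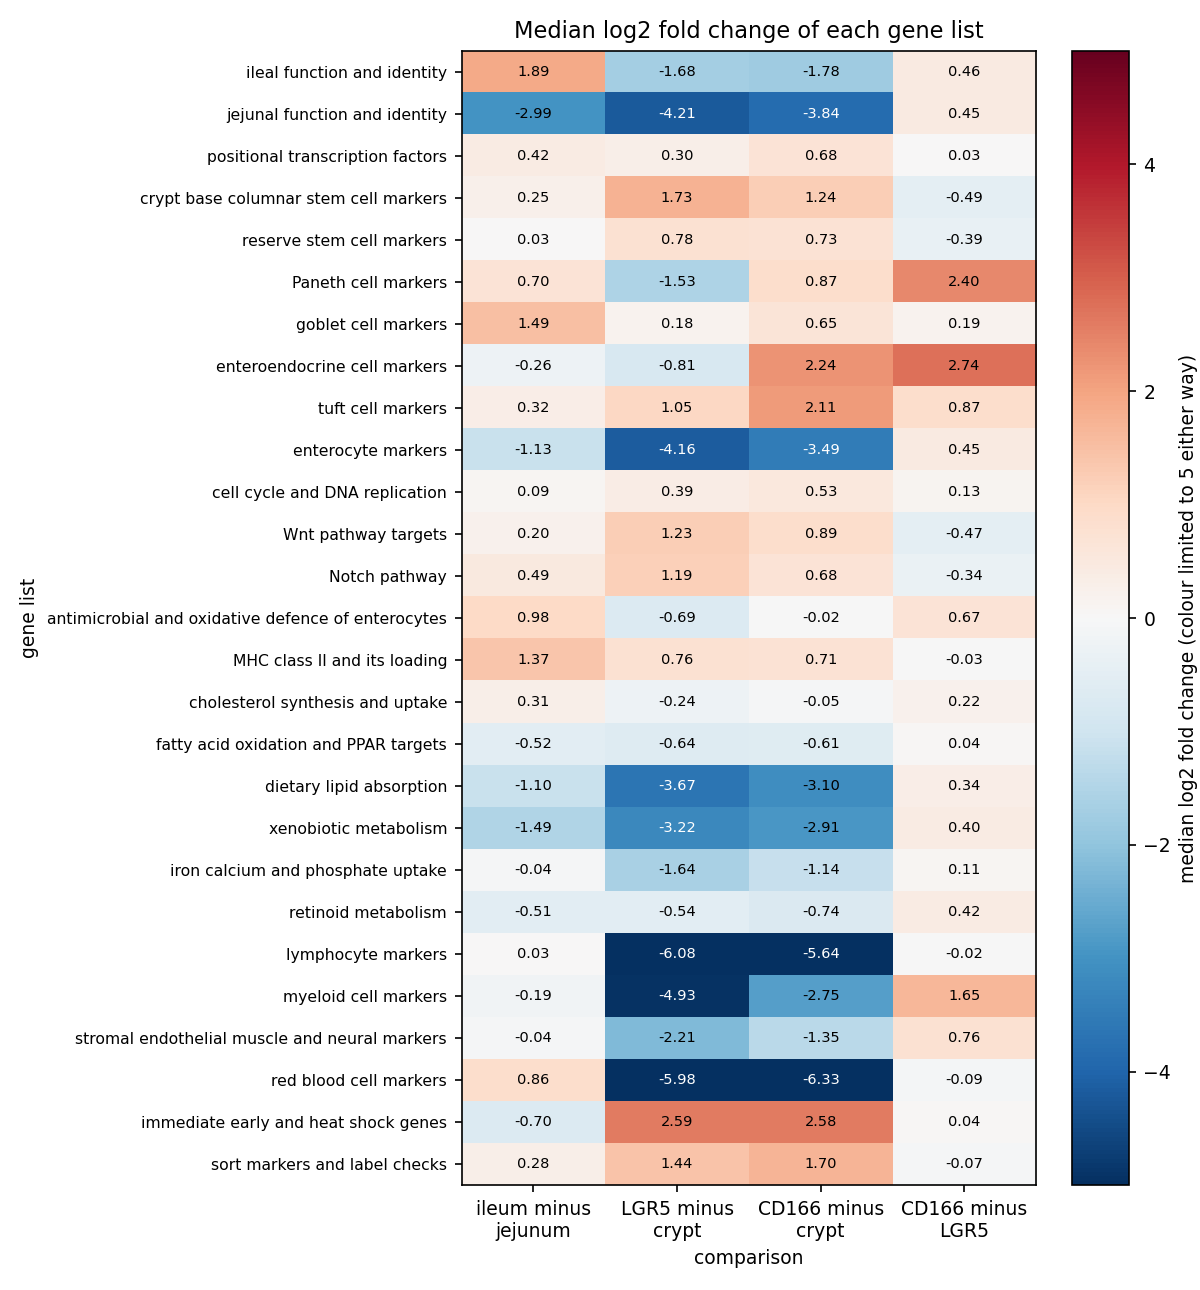
Median log2 fold change of each of the 27 gene lists (one per line) in the 4 comparisons named on the horizontal axis, with colour limited to 5 either way. Between CD166 and LGR5 cells the highest medians are those of the enteroendocrine (2.74) and Paneth (2.40) lists.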

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

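The planned test in this part is the interaction test; the splits of the libraries and the tests of explanations were chosen after the results were seen.

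Unc5b and C530008M17Rik stood out because the test of the interaction found that their difference between ileum and jejunum depended on the population (edgeR adjusted p = 0.0367 for each). Unc5b was at 32.5 and 26.8 CPM in ileal and 3.82 and 4.01 CPM in jejunal LGR5 cells, and at 23.2 and 20.1 against 6.54 and 5.14 CPM in CD166 cells. In the 6 crypt libraries it lay between 23.8 and 37.7 CPM. C530008M17Rik was at 24.3 and 37.0 CPM in ileal and 5.01 and 5.73 CPM in jejunal LGR5 cells, at 24.3 to 34.1 CPM in the 4 CD166 libraries and at 78.1 to 88.0 CPM in crypt. Under the alternatives this count of 2 ran from 0 to 70. Single genes were not tested for 1 library far from its group, since each group holds 2 or 3 libraries.

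The first pattern weighed is that the library labelled ileum crypt 3 has a jejunal profile. On an axis built from the 173 ileal and 182 jejunal genes called in both sorted populations in a fit of the sorted libraries alone, scaled so that jejunal sorted libraries average 0 and ileal ones 1, the other ileum crypt libraries lay at 0.74 and 0.70 and this library at -0.04, as a single wrong region label would give. A swap with a jejunum crypt library is argued against, since the highest of those libraries lay at -0.03. It differed beyond noise from jejunum crypt 1 at 17.4% of genes, the lowest of 91 pairs, which is consistent with one tissue sample under 2 labels. A position nearer the middle of the gut stays open as a biological explanation and was not tested; Osr2 was at 96.0 and 98.9 CPM in this pair, against 123 and 160 CPM in the other ileal and 5.39 and 18.8 CPM in the other jejunal crypt libraries.

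The second pattern is that Xist was high in 10 of 14 libraries given as male. In ileum crypt 1 and jejunum crypt 2 the Y-linked genes Ddx3y, Kdm5d and Eif2s3y reached at most 0.16 CPM, against 25.8 to 57.0 CPM in the other 4 crypt libraries, as female mice would give. In the 8 sorted libraries Xist was at 203.6 to 1483 CPM while Y-linked genes were at 2.15 CPM or more, which is consistent with mice of both sexes in each sorted library. The number of mice per library is not given, and no other explanation was tested.

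The third pattern is that enteroendocrine and Paneth genes were higher in CD166 than in LGR5 cells. A lower share of stem cells stays open. The upper quartile of the goblet list's log2 fold changes was 0.52, below the lower quartile of the enteroendocrine list, 1.83. This cannot decide, since a marker's rise also depends on how much of its cell type the LGR5 cells held. Mean log2 goblet levels were 7.4 and 7.08 in jejunal CD166 against 6.03 and 5.55 in jejunal LGR5 libraries. In the ileum they were 7.59 and 8.19 against 7.53 and 9.08. All 24 stem cell markers were lower in CD166 cells (median -0.49, camera adjusted p = 3.3e-07, adjusted p = 0.67 with an estimated correlation). A single odd CD166 library is argued against, since the lowest CD166 library lay 0.76 above the highest LGR5 library in the mean log2 level of the enteroendocrine list. A sort gate that takes in endocrine and Paneth cells, or expression of these genes by the sorted stem cells, stays open, and the design does not part them. The gate is described as low in CD24. Cd24a RNA was 3.06-fold higher in CD166 than in crypt cells (log2 1.62 ± 0.28) and differed by 0.62 ± 0.31 from LGR5 cells (adjusted p = 0.593). These RNA values do not test a gate on protein, and the crypt cells are a mixture with more enterocyte and immune transcripts.

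Other splits of the same libraries tested whether arbitrary splits call as many genes. Over all populations 100 of the 360 possible splits into regions were tried. Of these, 2 called as many genes as the real one, itself included, which called 739. This share of 0.02 does not exclude chance, since it covers part of the splits and takes the libraries as independent, which the labels do not state. The highest other split called 1094. That split exchanged the library labelled ileum crypt 3 with jejunum crypt 2. It moves the library with a jejunal profile to the jejunal side and puts both crypt libraries with high Xist on the ileal side, and which of these raised the count was not separated. The region count was 1269 without the library labelled ileum crypt 3, 1298 with a term for the crypt libraries high in Xist and 1224 without them. In crypt cells there are 10 splits, too few for a share under 0.05; the real split called 0 and the highest other, the same exchange, 451. For LGR5 against crypt 1 of 100 splits, the real one, called as many as 4639 (highest other 547). For CD166 against crypt 1 of 100, again the real one, called as many as 4439 (highest other 904). No other split reached the real count in either, although these shares also take the libraries as independent. For CD166 against LGR5 there are 18 splits, too few for a share under 0.05; 1, the real one, called 238 and the highest other 72.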

How the results depend on the processing

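The alternatives named here as added were chosen after the data were seen; the others were planned. Between the TMM and DESeq2 size factors the median of all genes moved by at most 0.042 in log2. No named gene that was called changed its direction under any alternative. No gene list was called in opposite directions by the main fit and an alternative. A change of direction in lists that lost their call was not counted. Of the called genes followed, the call held in every fit without 1 library for 34 of 78 between regions over all populations, 2 of 21 in LGR5, 0 of 3 in CD166, 41 of 54 for LGR5 against crypt, 42 of 50 for CD166 against crypt and 16 of 24 for CD166 against LGR5. It held in every other alternative, apart from the replicate block and the crossed numbers, for 53, 6, 3, 44, 42 and 22 of them. Where 1 library is left in a group, it is assumed to vary like the other groups. The cause of the differences below was not tested. Fits without a library or without other groups hold fewer libraries, which does not account for counts that rose. In fits of the compared groups alone, region counts rose from 103 to 1574 in LGR5 and from 3 to 571 in CD166 cells. CD166 against LGR5 rose from 238 to 575. LGR5 and CD166 against crypt fell from 4639 to 3666 and from 4439 to 3475, and crypt stayed at 0. The main fit shares its spread over all 6 groups, so 103 and 3 depend on the crypt libraries too.

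Counts of genes called by edgeR moved as follows. Between regions over all populations the count of 739 was 1410 with DESeq2, 138 to 1269 without 1 library, 426 with the replicate block, and in added alternatives 1402 without the near-identical pair, 1224 without the crypt libraries high in Xist, 1298 with a term for them and 1752 with weights per library. In crypt the count of 0 (1899 at an unadjusted p under 0.05; limma-voom 0) was 323 with DESeq2, 0 to 614 without 1 library, 863 without the pair, 83 without the Xist-high libraries and 2 with their term. In LGR5 the count of 103 was 773 with DESeq2, 30 with limma-voom, 1574 in a fit of those groups alone, 0 with the replicate block and 2 to 159 without 1 of its own libraries; added alternatives gave 357 without the library labelled ileum crypt 3, 399, 535 and 480 (pair, Xist-high libraries, their term), 210 with limma on the deposited log2 values, 1223 with sorted libraries alone and 1506 with weights. In CD166 the count of 3 was 13 with no filter, 186 with DESeq2, 47 with limma-voom, 571 in a fit of those groups alone, 0 with the replicate block and 0 without any 1 of its own libraries; added alternatives gave 112, 142, 73, 58, 14, 540 and 144 in the same order. The interaction count of 2 was 70 with DESeq2, 0 with limma-voom, 0 with the replicate block, 0 to 15 without 1 library, 33 and 5 for the Xist-high libraries and their term, 1 with limma on log2 values and 5 with weights. The count for LGR5 against crypt (4639) ran from 2421 to 5032 without 1 library, and that for CD166 against crypt (4439) from 2769 to 5112. For CD166 against LGR5 the count of 238 was 421 with DESeq2, 575 in a fit of those groups alone, 85 to 252 without 1 library, and in added alternatives 402, 394, 575 and 544 (Xist-high libraries, their term, sorted libraries alone, weights).

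Of the lists, 16 of 27 were called between regions and 53 of 81 tests between populations; with an estimated correlation these were 0 and 1. Genes called in LGR5 cells had the same sign in crypt and CD166 cells at 90.3% and 88.3%, and at 79.1% and 72.8% with a separate fit per population. The replicate block assumes that equal numbers pair ileal and jejunal libraries. Deviations of same-numbered libraries from their group correlated at -0.33, -0.40 and 0.33 in crypt, -0.22 in LGR5 and -0.30 in CD166, so equal numbers give no sign of pairing. Across unequal numbers the highest value was 0.55, between ileum crypt 1 and jejunum crypt 2, the crypt libraries high in Xist. Crossed pairs stood at 0.22 in LGR5 and 0.3 in CD166. With 2 libraries in a group, their deviations are exact opposites, so a crossed value is the same-number value with its sign changed. The crossed values are therefore no separate evidence for crossed pairing. Pairing across numbers, by mouse or by batch, stays open. With crossed numbers in the sorted populations, an added alternative, the counts were 545, 50 and 0 over all populations, in LGR5 and in CD166. The block gave 0 genes in crypt, 3901 and 3638 for LGR5 and CD166 against crypt, 255 for CD166 against LGR5, and 15 and 55 lists. The alternatives on RPKM values could not be run. In alternatives other than leaving out 1 library, 70 of 120 counts stayed equal or within 1.5 times. When 1 library was left out, 53 stayed so and 50 moved further. These include counts of 0 that stayed 0, and shares of genes with the same sign, which were judged in percentage points instead. In simulated data of this design 4-fold changes were recovered at 61.6% to 87.0% and 2-fold changes at 6.8% to 64.8%. Differences between populations and unlike libraries were not modelled there, so the real recovery may be lower.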

Other observations

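The genes in this part were picked after their values were seen, and apart from those given as list members none belongs to the lists fixed in advance; all values come from the planned edgeR fit.

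Retinol dehydrogenase genes went in opposite directions between the regions. Rdh9 was 7.12-fold higher in the ileum over all populations (log2 2.83 ± 0.28, adjusted p = 0.00195) and Rdh1 11.0-fold higher (3.45 ± 0.40), while Rdh7, a list member, fell (-2.69 ± 0.47); the family has near-identical copies, so reads may be shared, and the count of 3 genes called in CD166 cells, which includes Rdh9, ran from 0 to 571 under the alternatives. Rdh9 stood at 1.03 to 1.94 CPM in the 4 jejunal sorted libraries and at 19.8 to 37.9 CPM in the ileal ones. In crypt cells it lay between 19.8 and 50.3 CPM in both regions. Among single genes of other functions, Bex1 was 56.4-fold higher in the ileum (5.82 ± 0.68) and the adenylate cyclase gene Adcy8 18.2-fold higher (4.18 ± 0.45). The ion channel gene Trpa1 was 19.4-fold lower (-4.28 ± 0.69) and Fstl1 9.55-fold lower (-3.26 ± 0.33). Among metabolic genes, the alkaline phosphatase gene Akp3 (-6.10 ± 1.13, adjusted p = 0.0138), Adh4 (-3.93 ± 0.58) and the fetal protein gene Afp (-4.01 ± 0.69) were lower in the ileum. Rdh9, Rdh1, Bex1, Adcy8, Trpa1, Fstl1 and Adh4 were called in each of the 14 fits without 1 library; Afp lost the call without ileum LGR5 2 or jejunum LGR5 2, and Akp3 without 5 sorted libraries.

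Single genes outside the enteroendocrine list were also higher in CD166 than in LGR5 cells. The amylin gene Iapp was 85.5-fold higher (log2 6.42 ± 0.52, adjusted p = 0.000325), the signalling regulator gene Rgs4 28.8-fold (4.85 ± 0.36), the granule gene Scg5 20.8-fold (4.38 ± 0.49), the imprinted gene Peg3 10.3-fold (3.36 ± 0.31) and the calcium channel subunit gene Cacna2d1 9.24-fold (3.21 ± 0.36). The prohormone convertase gene Pcsk1 was 4.05-fold higher (2.02 ± 0.28), and Reg4, a list member among the defence genes, 5.05-fold (2.34 ± 0.32). These 7 were called in each fit without 1 library. Slc6a19, an amino acid transporter gene of enterocytes, was 8.53-fold higher (3.09 ± 0.48), and lost the call without any 1 of the 4 LGR5 libraries.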
